A study of Homo sapiens with 4 samples.

How the data were processed

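RNA of human saliva exosomes was measured on 4 Affymetrix arrays, all in 1 group. Exosomes are small vesicles released by cells, and here, per the labels' protocols, they were purified by centrifugation from saliva pooled from healthy people. The RNA went through 2 rounds of amplification before biotin labelling and hybridization. The labels call the arrays biological replicates 1 to 4 and give each a batch number equal to its replicate number, so batch and replicate cannot be told apart. Nothing in the labels says whether different people gave to each pool, and the spread between arrays may therefore be partly technical. The number of arrays limits the precision of every value.

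The values are probe set intensities deposited by the authors on a linear scale, with GCRMA named as the software in the submitters' processing notes. GCRMA corrects probe brightness for background with the help of probe sequence and joins the probes of a set into 1 signal. Its version, its settings and any scaling between arrays were not given in the sources used here. The arrays were not on a common distribution: their median signals were 5.12, 5.61, 5.76 and 5.84 for replicates 1 to 4, and their 95th percentiles were 17.7, 27.8, 35.7 and 101. The design had allowed for log2 or linear values. As the values were linear, 1 was added to each and the log2 taken, so differences between low signals are understated. A pseudocount of 16 was the alternative. No pair of arrays shared more than 0.669% of its values exactly, so no array was a copy of another.

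The table held 54675 probe sets, of which 62 were manufacturer's controls and 54613 were tested. The platform annotation gave 41097 probe sets 1 gene symbol and 1801 several, and 11715 were unnamed here. Symbols were updated by Entrez identifier through the RefSeq gene table of the GRCh38.p14 assembly, where 41043 of the single-gene probe sets were found. A gene was named only from probe sets with 1 symbol, which gave 19740 genes. XIST, TSIX and Y-linked genes, 35 in all, were left out everywhere. Signal depends on a probe's own binding as well as on RNA amount, so an order of signals is not an order of abundance. Suffixes on probe set names mark shared probes: _s_at sets match several transcripts, often of 1 family, and _x_at sets hold probes that match unrelated transcripts as well. Probe sets without either suffix are called unmarked here, although a few of them carry other suffixes. No probe sequences or genome coordinates were used.

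Detection was defined against genes not expected in saliva. On each array the cutoff was the 95th percentile of 135 probe sets of olfactory receptor genes. The log2 signal minus the cutoff of its array was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, intercept only). The test was one-sided, with Benjamini-Hochberg adjustment over all 54613 probe sets at 0.05. A gene was counted as detected where any probe set of its own passed. A plain count of genes above the cutoff on all 4 arrays was made beside it. Because there was 1 group, no comparison between groups was made.

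For each of 25 gene lists, fixed with the tests and alternatives before the data were examined, the number of detected genes was set against 10000 random lists matched on probe sets per gene, in 6 strata. That permutation test was two-sided, with Benjamini-Hochberg adjustment over the lists, and 2.0e-04 is the smallest p it can give. Genes are not independent replicates, so these p-values describe these arrays. Whether a list's detected genes moved together between arrays was tested by the variance of the list mean against 10000 random lists of detected genes matched on signal. Control transcripts with probe sets at both ends gave the difference between 3′ and 5′ signal, tested with an exact sign-flip permutation. The TFRC control was not analysed here. A further control transcript is not reported here.

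Replicate 1 had almost no signal for human transcripts. Leaving out each replicate in turn had been planned, but to lead with the fit without replicate 1, and to run every other alternative on it as well, was decided after seeing the data. Results of the planned test over 4 arrays are given first. In the fit over 3 arrays, limma's prior degrees of freedom were 675, so the standard error of each gene was essentially that of the trend, and the very small adjusted p-values do not rest on that gene's own spread. In the fit over 4 arrays the trend reached an SD of 16.96 log2 units, above the largest observed SD of 5.31.

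The named genes were set by a rule: up to 4 detected genes per list with the highest mean signal, the 25 detected genes with the highest signal of all, and the 10 with the largest SD over the arrays among genes above the cutoff on at least 2 arrays. The value of a gene is that of its probe set with the highest mean. As no gene was detected over 4 arrays, the parts of the rule that need detected genes were applied to the fit without replicate 1. The SD was taken over all 4 arrays. Genes named outside it are said to be so where they appear.

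The scripts were tested on simulated data for the 54613 probe sets, with means and spread taken from replicates 2 to 4 and 200 probe sets raised above the cutoff by a known amount. With 4 arrays that all held the signal, 4.48% of probe sets at 1 log2 unit above the cutoff were recovered, 52.2% at 2 units and 100% at 4 units. With 3 arrays these shares were 2.99%, 43.3% and 100%. With 4 arrays of which 1 lacked the signal, limma recovered 0% at each of the 3 sizes. On that array all other probe sets with means near or above the cutoff were set to background too. This was harsher than the real replicate 1, where 19.3% of the detected probe sets lay above the cutoff. The 0% therefore gives no recovery rate for the real arrays. There were 0 false calls among 45213 probe sets without signal in each simulation. These had means below the cutoff by design and spread drawn from the fitted trend alone, so false calls were unlikely from the start. The count gives no error rate for the real calls. In the real fit over 3 arrays the largest observed SD was 4.17 log2 units, against 1.02 for the trend. Of 100 random gene lists run through the list test on 19740 genes, 1 had an unadjusted permutation p under 0.05 and 0 an adjusted one. In the test of list variation over 965 genes, 0 of 20 random lists passed.

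Alternatives changed 1 choice at a time: the 99th or 90th percentile of the olfactory receptor probe sets, fixed cutoffs of log2 4, 5 or 7, the 95th percentile of photoreceptor and lens probe sets, no _x_at or _s_at probe sets, quantile normalization or median-centring of the arrays, no trend in limma, no dim probe sets, and the median of a gene's probe sets. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.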

Results

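RNA carried by exosomes of pooled human saliva was profiled on 4 whole-transcriptome arrays, replicates 1 to 4 of 1 group, to describe which transcripts the vesicles contain. On replicates 1 to 4 in turn, 3981, 5137, 8967 and 8195 of 54613 probe sets lay above the cutoff set by olfactory receptor probe sets, or 7.29%, 9.41%, 16.4% and 15.0%. The cutoffs were log2 signals of 4.04, 4.29, 3.91 and 4.66.

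Many genes on the lists for salivary glands, squamous epithelium and neutrophils gave strong signals on replicates 2 to 4. Most of these gave almost none on replicate 1. Membership of a list does not show which cells released the RNA. SMR3B, a secreted salivary protein, had signals of 2.37, 4785, 4822 and 4757 on replicates 1 to 4. SPRR3, a cornified envelope protein of squamous epithelium, had 2.38, 5432, 6313 and 5268. S100A8, a calcium-binding protein abundant in neutrophils, had 2.30, 3058, 3891 and 8300. The ribosomal protein gene RPS10 had 3.47, 3637, 3862 and 5940. The list of salivary secretory genes had 1, 18, 20 and 20 of its 33 members above the cutoff on replicates 1 to 4, the neutrophil list 7, 32, 36 and 37 of 44, and the cytosolic ribosomal proteins 7, 48, 50 and 50 of 53. Photoreceptor and lens genes, which are not expected in saliva, had 4, 3, 3 and 1 of 50.

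The bacterial and phage spike-in controls, added at hybridization, did not follow this pattern. Their mean log2 signal over 18 probe sets was 11.50, 11.74, 11.45 and 9.10 on replicates 1 to 4. The control probe set for Alu, the commonest short repeat of the human genome, read 2129 on replicate 1 and 19181, 19776 and 19398 on the others.

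**Figure D1:**
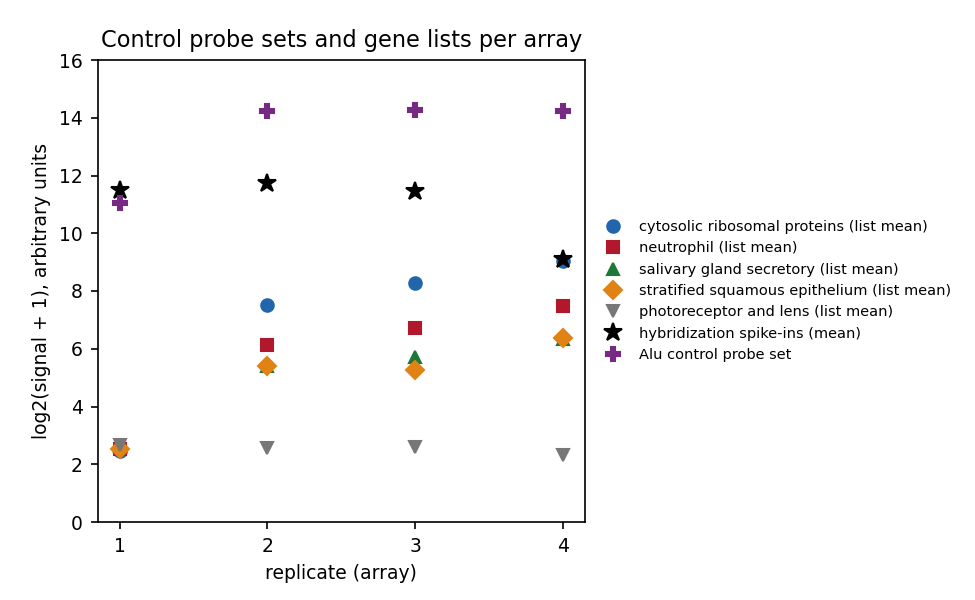
Log2(signal + 1) of control probe sets and mean log2 signal of 5 gene lists on each of the 4 arrays, with 1 point per array and no error bars. The spike-in mean is 11.50 on replicate 1 and 9.10 on replicate 4, while the ribosomal, neutrophil, salivary gland and squamous lists lie with the photoreceptor and lens list on replicate 1 only.

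Over all 4 arrays, the planned limma test detected 0 genes, and its smallest adjusted p was 1. This 0 depends on the variance trend, whose fitted SD reached 16.96 log2 units, above the largest observed SD of 5.31. NUMBL, for example, lay 8.89 log2 units above the cutoff at the mean, with a signal SD of 1.18. Limma gave it a standard error of 7.85. The 0 therefore does not show that no gene lay above background on every array. At an unadjusted p under 0.05 the planned test had 1237 of 54613 probe sets. Without the variance trend, limma detected 105 genes over the same arrays, and all 105 were also detected without replicate 1. Leaving out replicate 1 gave 965 genes, from 1454 probe sets, or 4.89% of 19740 genes, and 301 genes with replicate 3 left out as well. Leaving out replicate 2, 3 or 4 gave 0 genes each time in limma, with 206, 347 and 1093 probe sets at an unadjusted p under 0.05, and 38, 39 and 29 genes without the trend. The gene list test over 4 arrays had no detected gene to work with and so 0 lists past the threshold. The 105 genes found without the trend also gave 0 of 25 lists, with 0 lists at an unadjusted permutation p under 0.05 and a smallest p of 0.0590.

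Genes of salivary gland secretions were detected on replicates 2 to 4 more often than other genes. Of 33 measured, 16 were detected (17 adjusted over the list alone), where matched random lists had 1.07 (permutation p = 2.0e-04, adjusted p = 5.0e-04). SMR3B had a log2 signal of 12.23 ± 0.01 (SD, n = 3), and STATH, whose product statherin keeps calcium phosphate in solution, had 11.33 ± 0.61. The mucin gene MUC7 had 11.18 ± 0.27, with 1 of its 2 probe sets detected. PRB4, a basic proline-rich protein read by an _x_at probe set, had 9.33 ± 0.49. ZG16B, FDCSP, HTN1, PIP, PRB1, BPIFA2, CST4, PIGR, KLK1, PRB3, OPRPN and CA6 made up the rest. CA6 is treated apart below as it also gave signal on replicate 1. Without _x_at and _s_at probe sets, 10 of 24 salivary genes were detected (adjusted permutation p = 0.0010). Without replicate 3 as well, 11 of 33 were detected (adjusted permutation p = 5.6e-04).

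On the list for squamous epithelium, the lining of the mouth, 14 of 47 measured genes were detected (20 adjusted over the list alone). Random lists had 1.80 (permutation p = 2.0e-04, adjusted p = 5.0e-04). SPRR3 had a log2 signal of 12.47 ± 0.14 (SD, n = 3), CSTA, the protease inhibitor cystatin A, 12.41 ± 0.15, and PPL, the desmosome-linked protein periplakin, 11.93 ± 0.11. The envelope protein gene SPRR1B had 11.58 ± 0.54. The keratin genes KRT4 and KRT13 of non-cornified mouth epithelium were detected too, with SPRR1A, CRNN, CNFN, EMP1, MAL, KRT10, S100A2 and KRT80. Without _x_at and _s_at probe sets, 8 of 37 squamous genes were detected (adjusted permutation p = 0.0010). Without replicate 3 as well, 10 of 47 were detected (adjusted permutation p = 5.6e-04).

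Neutrophil genes were detected in 26 of 44 cases (30 adjusted over the list alone), against 2.04 in random lists (permutation p = 2.0e-04, adjusted p = 5.0e-04). S100A8 had a log2 signal of 12.17 ± 0.75 (SD, n = 3), the chemokine gene CXCL8 12.07 ± 0.49, G0S2, an inhibitor of lipolysis, 11.18 ± 0.48, and SRGN, the granule proteoglycan serglycin, 10.68 ± 0.98. Surface receptors of neutrophils were among the rest, such as FCGR3B, CXCR1, FPR1 and CSF3R. CXCL8 was read by an _x_at probe set, and 1 of its 2 probe sets was detected. Without replicate 3 as well, 17 of 44 neutrophil genes were detected (adjusted permutation p = 5.6e-04). Without _x_at and _s_at probe sets, 18 of 33 were detected (adjusted permutation p = 0.0010). Of 21 monocyte and macrophage genes, 2 were detected, CLEC7A and CD86, against 1.13 in random lists (permutation p = 0.624, adjusted p = 0.780). This count was 1, 0 and 1 with replicate 2, 3 or 4 left out as well.

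Cytosolic ribosomal protein genes were detected in 45 of 53 cases (48 adjusted over the list alone), against 2.67 in random lists, and translation factors in 15 of 34 (18 adjusted over the list alone), against 2.33. Both had a permutation p of 2.0e-04 and an adjusted p of 5.0e-04. RPS10 had a log2 signal of 12.09 ± 0.39 (SD, n = 3), RPL10A 12.08 ± 0.39, RPL14 12.05 ± 0.64 and RPS28 11.87 ± 0.45. Among the factors, TPT1 had 12.70 ± 0.33, EEF1A1, the carrier of aminoacyl-tRNA, 10.43 ± 0.62, EIF3L 9.75 ± 0.17 and PABPC1, which binds poly(A) tails, 8.85 ± 0.39. Mitochondrial ribosomal proteins were detected in 5 of 73 cases (6 adjusted over the list alone), against 3.29 in random lists (permutation p = 0.467, adjusted p = 0.614), and in 8, 1 and 2 with replicate 2, 3 or 4 left out as well, where the list did not pass either. Most ribosomal probe sets are of the _s_at or _x_at kind, which related genes or processed pseudogenes can share. Without such probe sets 8 of 30 ribosomal protein genes were detected (adjusted permutation p = 0.0010) and 3 of 27 translation factors (adjusted permutation p = 0.130).

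Nuclear genes of the respiratory chain were detected in 19 of 68 cases (23 adjusted over the list alone), against 3.34 in random lists. UQCR11 had a log2 signal of 9.16 ± 0.29 (SD, n = 3), NDUFB8 8.38 ± 0.28, COX7A2 8.23 ± 0.54 and COX7C 8.11 ± 1.02. Genes of the actin cytoskeleton were detected in 19 of 34 cases (20 adjusted over the list alone), against 2.00. ACTB had 9.72 ± 0.46, ARPC2 of the Arp2/3 complex 9.69 ± 0.43, the myosin light chain gene MYL12A 9.32 ± 0.16 and RAC2, a GTPase of blood cells, 8.48 ± 0.52. Each list had a permutation p of 2.0e-04 and an adjusted p of 5.0e-04. At a fixed cutoff of log2 7, 0 of 68 respiratory chain genes were detected (adjusted permutation p = 1). Without _x_at and _s_at probe sets, 6 of 56 respiratory chain genes (adjusted permutation p = 0.0050) and 6 of 28 actin genes (adjusted permutation p = 0.0010) were detected. Without replicate 3 as well, the counts were 8 of 68 respiratory chain genes and 8 of 34 actin genes (adjusted permutation p = 5.6e-04 for each).

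Endosomal sorting and exosome genes were detected in 11 of 49 cases (12 adjusted over the list alone), against 2.63 in random lists (permutation p = 2.0e-04, adjusted p = 5.0e-04). SDCBP, which encodes syntenin, a protein of exosome formation, had a log2 signal of 9.35 ± 1.21 (SD, n = 3). The annexin gene ANXA11 had 8.88 ± 0.19, the recycling endosome GTPase RAB11A 8.42 ± 0.71 and ANXA2 8.03 ± 0.47. The rest were LAMP1, RAB27A, CD53, RAB5A, FLOT1, CHMP5 and VPS37C. The list had 3 of 39 detected without _x_at and _s_at probe sets (adjusted permutation p = 0.240) and 3 of 49 by the median of a gene's probe sets (adjusted permutation p = 0.276). At a fixed cutoff of log2 7 it had 0 of 49 (adjusted permutation p = 1). Without replicate 3 as well it had 6 of 49 (adjusted permutation p = 0.0010).

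Immediate early genes, which cells induce within minutes of a stimulus, were detected in 11 of 24 cases (11 adjusted over the list alone), against 1.38 in random lists (permutation p = 2.0e-04, adjusted p = 5.0e-04). ZFP36, which speeds mRNA decay, had a log2 signal of 10.91 ± 0.96 (SD, n = 3), the phosphatase gene DUSP1 10.26 ± 0.91, GADD45B 9.40 ± 0.07 and IER3 8.29 ± 0.47. Interferon-stimulated genes were detected in 6 of 27 cases (7 adjusted over the list alone), against 1.03 (permutation p = 4.0e-04, adjusted p = 9.1e-04), namely IFITM1, IFIT2, IRF7, MX2, ISG15 and IFITM3. Their log2 signals were lower, at 8.17 ± 0.78 for IFITM1, 7.11 ± 0.93 for IFIT2, 6.63 ± 0.68 for IRF7 and 6.62 ± 0.70 for MX2. Without _x_at and _s_at probe sets, 1 of 16 immediate early genes was detected (adjusted permutation p = 1) and 2 of 23 interferon-stimulated genes (adjusted permutation p = 0.332). Without replicate 3 as well, 6 of 24 immediate early genes (adjusted permutation p = 5.6e-04) and 1 of 27 interferon-stimulated genes (adjusted permutation p = 1) were detected.

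A panel of transcripts earlier proposed as salivary markers of oral cancer had 6 of 7 members detected (7 adjusted over the list alone), against 0.346 in random lists (permutation p = 2.0e-04, adjusted p = 5.0e-04). SAT1, an enzyme of polyamine catabolism, had a log2 signal of 11.68 ± 0.55 (SD, n = 3) and the cytokine gene IL1B 10.66 ± 0.23. CXCL8 and IL1B are also on the neutrophil list and DUSP1 is on the immediate early list, so these counts overlap. OAZ1 and S100P were the other members detected. Without _x_at and _s_at probe sets, only 2 members were still measured, and 2 of 2 were detected (adjusted permutation p = 0.0042).

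Further lists did not pass. Proteasome genes were detected in 5 of 35 cases (6 adjusted over the list alone; permutation p = 0.0390, adjusted p = 0.0812), with PSMA7 at a log2 signal of 7.15 ± 0.37 (SD, n = 3). Heat shock and chaperone genes were detected in 5 of 30 cases (7 adjusted over the list alone; permutation p = 0.0488, adjusted p = 0.0938), with UBB, a polyubiquitin gene, at 9.04 ± 0.65 and HSP90AA1 at 8.02 ± 0.51. Iron storage and handling had 2 of 12 (adjusted permutation p = 0.585), FTL of ferritin at 9.08 ± 0.12 and SLC11A1 at 7.66 ± 0.22. Stroma and vessel genes had 2 of 22 (adjusted permutation p = 1), MYH11 and PECAM1, and replication-dependent histones 2 of 27 (adjusted permutation p = 0.574), H2BC12 and H1-2. MYH11 was read by an _x_at probe set, with 1 of its 7 probe sets detected, so its signal cannot be taken as a level of that gene. PECAM1 had 1 of 5 probe sets detected. Adjusted over the list alone, the counts of these last 3 lists and of the monocyte list were unchanged at 2. With replicate 2 left out as well, heat shock genes passed with 8 of 30 (adjusted permutation p = 0.0025). With replicate 3 left out as well they had 2 of 30, proteasome genes 0 of 35, stroma and vessel genes 1 of 22 and histones 0 of 27.

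No gene was detected in 7 lists. They were T and NK cells (21 measured), B and plasma cells (18), erythrocytes (12), cell division (36), nuclear long noncoding RNAs (7), photoreceptor and lens (50) and liver secreted proteins (38). Limma had 0 genes in each of them adjusted over the list alone and 0 without its trend. At an unadjusted p under 0.05 it had 1 nuclear noncoding gene, 1 photoreceptor and lens gene and 0 in the other lists. Random lists had 0.552 to 1.77 detected genes and reached down to 0, so the list test could not have shown fewer in any of the 7. It had 0 of them at an unadjusted permutation p under 0.05, with a smallest p of 0.323. The 102 olfactory receptor genes, which set the cutoff, had 0 detected.

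**Figure D2:**
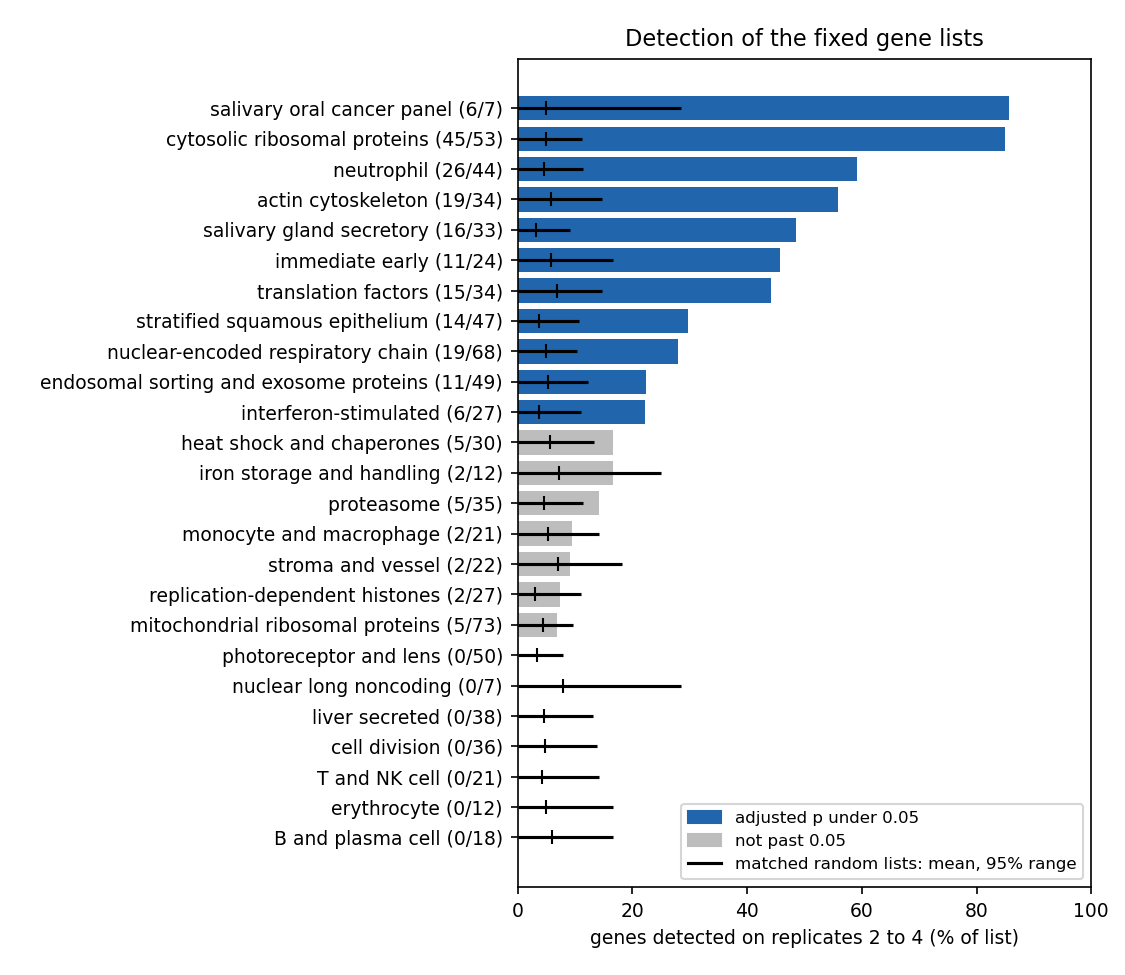
Share of the measured genes of each fixed list that limma detected on replicates 2 to 4, in percent, with counts in parentheses. Horizontal lines give the mean and 95% range of 10000 matched random lists. In 11 lists, from interferon-stimulated genes (6 of 27) to the oral cancer panel (6 of 7), the adjusted permutation p was under 0.05.

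**Figure D3:**
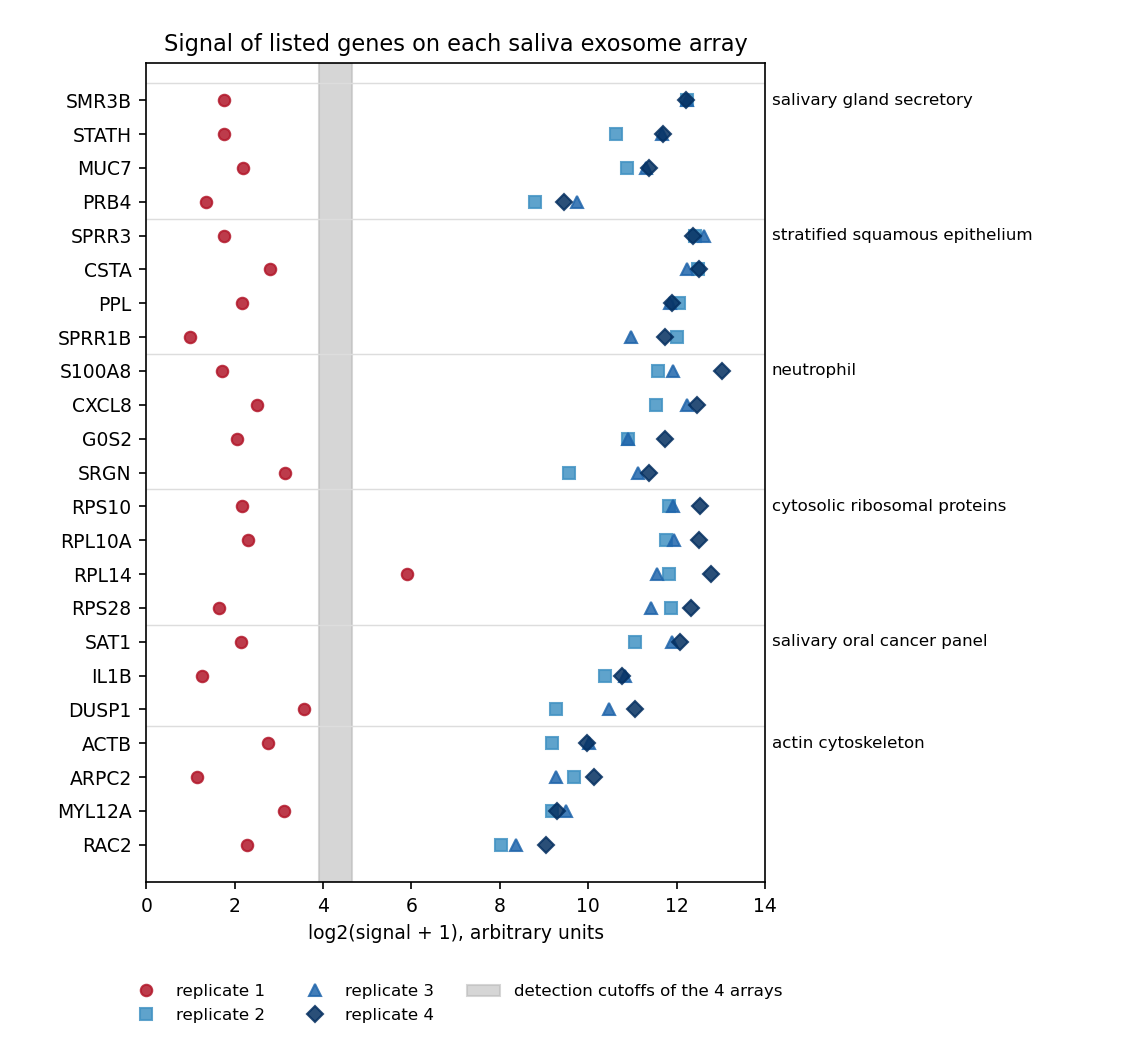
Log2(signal + 1) of named genes from 6 lists, 1 point per array, with the detection cutoffs of the 4 arrays (3.91 to 4.66) as a grey band. The points of replicate 1 lie left of the band for each gene drawn except RPL14, and those of replicates 2 to 4 lie right of it.

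The highest signals of all came from probe sets that can bind unrelated transcripts. Of the 25 genes with the highest mean signal on replicates 2 to 4, 21 were read by _x_at probe sets, 2 by _s_at and 2 by unmarked ones. NUMBL led with a log2 signal of 13.70 ± 0.13 (SD, n = 3), before the mismatch repair gene MSH3 with 13.50 ± 0.19, the ferritin heavy chain pseudogene FTH1P5 with 13.40 ± 0.14 and the kinase subunit gene PRKAR2A with 13.23 ± 0.05. Of 20 such _x_at genes with other probe sets, 18 had no other probe set detected, so these signals cannot be taken as levels of the named genes. The unmarked ones were SMR3B and CSTA. Over all detected genes with more than 1 probe set, 36 of 717 had every probe set detected. Partial detection was therefore not particular to the leading _x_at genes. Many of the other genes named here also rest on 1 detected probe set among several.

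Genes above the cutoff on all 4 arrays numbered 533, or 2.70% of 19740, and 197 of them were also detected without replicate 1. They included RPL14, with signals of 58.4, 3622, 2994 and 6994 on replicates 1 to 4, MRPS15 with 86.5, 253, 323 and 173, and MSH3 with 1158, 12077, 10010 and 12930. RPL14 and MSH3 were read by _x_at probe sets and MRPS15 by an _s_at one. Without such probe sets the 533 genes became 273. With all probe sets, the count on all 4 arrays was 1 of 50 photoreceptor and lens genes, 0 of 38 liver genes and 0 of 102 olfactory receptor genes. Ribosomal proteins had 5 of 53 (permutation p = 0.0312, adjusted p = 0.780), and 0 of 25 lists passed after adjustment. Without replicate 4, 945 genes were above the cutoff on the other 3 arrays. On replicates 2 to 4 alone it was 2040 genes, and 3352 on replicates 3 and 4.

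Across all 54613 probe sets, signals on replicates 2 to 4 were related to each other and only weakly to those on replicate 1. Pearson's r of log2 signals was 0.65 for replicates 2 and 3, 0.59 for 2 and 4 and 0.65 for 3 and 4, and Spearman's rho was 0.45, 0.43 and 0.49. Replicate 1 had an r of 0.32, 0.21 and 0.10 with replicates 2, 3 and 4, and a rho of 0.27, 0.18 and 0.11. Probe sets are not independent replicates, so no p is given. The median SD of log2 signal over replicates 2 to 4 for the 965 detected genes was 0.73, with a 10th to 90th percentile range of 0.29 to 1.16.

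Ribosomal protein genes differed between replicates 2 to 4 as a group. The mean of the 45 detected genes stood at -0.79, 0.00 and 0.79 log2 units from its average on replicates 2, 3 and 4. Its SD was 0.79, against a median of 0.46 for random lists of detected genes with similar signal (permutation p = 1.0e-04, the smallest possible, adjusted p = 0.0014). The squamous list of 14 genes had an SD of 0.11 (adjusted permutation p = 1.00) and the neutrophil list of 26 genes 0.58 (adjusted permutation p = 0.469). After quantile normalization of the arrays the ribosomal list stood at -0.28, -0.18 and 0.46, with an SD of 0.40 against 0.08 for random lists (adjusted permutation p = 0.0014). The squamous list then passed too, with an SD of 0.30 against 0.09 for random lists (adjusted permutation p = 0.0119). Without that step none of the lists tested passed except ribosomal proteins. Over 4 arrays the test could not be run, as no gene was detected; with all measured members in place of detected ones, 11 lists passed, among them ribosomal proteins at -4.22 log2 units on replicate 1.

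The control transcripts ACTB and GAPDH, a glycolytic enzyme, were read at their 3′ ends but not above background at their 5′ ends on replicates 2 to 4. The 3′ probe set of ACTB had signals of 233, 354 and 365 there, and its 5′ probe set 5.62, 7.17 and 8.13. For GAPDH the 3′ probe set had 65.2, 57.3 and 148 and the 5′ probe set 13.4, 8.87 and 15.4. The cutoffs of these arrays were signals of 18.6, 13.98 and 24.2. Replicate 1, with a cutoff of 15.5, did not show this. Its 3′ probe sets read 6.02 for ACTB and 2.46 for GAPDH, and its 5′ probe sets 8.36 for ACTB and, above the cutoff, 23.3 for GAPDH. The planned difference of 3′ minus 5′ log2 signal was 3.87 ± 2.86 for ACTB (SD, n = 4, exact sign-flip p = 0.25) and 1.28 ± 2.76 for GAPDH (exact p = 0.5), where the smallest exact p that 4 arrays allow is 0.125. Without replicate 1 it was 5.30 ± 0.15 for ACTB (SD, n = 3) and 2.65 ± 0.50 for GAPDH. It sets different probes against each other, with 5′ signals mostly in the background, and so does not measure a ratio of transcript ends.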

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

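Tests of the replicate 4, spike-in and replicate 1 patterns below, and the test on the Alu repeat, were chosen after the results were seen; the test of _x_at against _s_at probe sets was written before its result was seen.

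Each value on the 4 arrays was checked for 1 array far from the rest: the gap between the extreme array and its nearest neighbour was divided by the whole range, and the ratio was set against Dixon's critical value, which chance exceeds in about 1 in 20 groups. Of 106 gene values, 63 exceeded it, and in all 63 replicate 1 was the lowest array. These genes were named mostly for high signal on replicates 2 to 4, and some for the largest SD over all 4 arrays. Both choices favour genes that are low on replicate 1, so the direction was largely set by the selection. The arrays are shared as well, so the 63 are not independent and cannot be set against a rate of 1 in 20. On the salivary gland and squamous lists the ratio was 1.00 for SMR3B, 0.89 for STATH, 0.95 for MUC7, 0.89 for PRB4, 0.98 for SPRR3, 0.97 for CSTA, 0.98 for PPL and 0.91 for SPRR1B. On the neutrophil, oral cancer and immediate early lists it was 0.87 for S100A8, 0.91 for CXCL8, 0.91 for G0S2, 0.95 for IL1B, 0.90 for SAT1, 0.98 for GADD45B and 0.83 for IER3. Genes of translation and of the respiratory chain had 0.93 for RPS10, 0.93 for RPL10A, 0.92 for RPS28, 0.88 for RPL24, 0.93 for TPT1, 0.86 for EEF1A1, 0.96 for EIF3L, 0.88 for PABPC1, 0.93 for UQCR11 and 0.88 for NDUFB8. Genes of the other lists had 0.89 for ACTB, 0.90 for ARPC2, 0.95 for MYL12A, 0.85 for RAC2, 0.94 for ANXA11, 0.86 for PSMA7, 0.96 for DNAJB1, 0.97 for FTL, 0.93 for SLC11A1 and 0.84 for H2BC12. Genes outside the lists had 0.88 for SFN, 0.94 for CSTB, 0.90 for GLTP, 0.83 for SOCS3, 0.92 for ANXA1, 0.85 for GNG10, 0.94 for RND3 and 0.88 for RNASET2. The genes with the highest signals, read largely by _x_at probe sets, had 0.87 for MYH11, 0.90 for NUMBL, 0.89 for MSH3, 0.97 for FTH1P5, 0.96 for PRKAR2A, 0.96 for ANAPC16, 0.92 for HUWE1, 0.99 for CMBL, 0.90 for DIP2A, 0.92 for FBXW12, 0.92 for POGZ, 0.93 for TMT1A, 0.94 for DMC1, 0.93 for MBTD1, 0.97 for CGAS, 0.96 for IPO9, 0.88 for LOC100289518, 0.85 for INTS4, 0.95 for ATF7IP and 0.86 for SMURF1.

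Replicate 1 was also lowest in the Alu control (0.99), in the 3′ minus 5′ difference of ACTB (0.95) and GAPDH (0.84), and in the number of list members above the cutoff. That ratio was 0.89 for salivary gland, 0.83 for neutrophil, 0.95 for ribosomal protein, 0.88 for translation factor and 0.85 for actin genes, and 1 for the oral cancer panel. Replicate 4 was lowest in spike-in signal (0.89). In all, 73 of 138 values exceeded the limit. The Alu control belongs to no comparison of the study, and it lay at least 7.01 log2 units above the cutoff on each array.

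Replicate 1 lacked most of the human transcripts detected on the other arrays. A failed hybridization or scan would dim the spike-ins too, but their median difference from the mean of replicates 2 and 3 was -0.12 log2 units. A single scale factor would move detected genes and spike-ins alike. Against the mean of replicates 2 to 4, the median difference was -4.50 log2 units for detected genes and 0.82 for spike-ins. The first minus the second was -5.32, which argues against a single scale factor. The low spike-ins of replicate 4 enlarge this value, and the detected genes were chosen for high signal on replicates 2 to 4. Too little labelled human RNA on this array may account for the pattern. Counting any probe set of a gene, 25.8% of the detected genes had one above its cutoff, beside 14.3% of all genes. That share lies between those set for and against the explanation. Of the detected probe sets themselves, 19.3% lay above the cutoff, beside 7.29% of all probe sets. This is just under the share set for the explanation, which was written for genes. The outcome depends on the unit counted, and the explanation stays open. Less RNA in saliva pool 1 itself cannot be told apart from a loss in the laboratory, because the number of arrays hybridized from pool 1 was 1, and no biological explanation could be tested in a design of 1 group.

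Probe sets marked _x_at led the signals. If shared sequence set their signals, the unmarked probe sets of the same genes could stay silent more often than those beside _s_at probe sets; they were detected in 7.19% of 153 genes, against 9.5% of 200 genes for _s_at (Fisher's exact p = 0.564), which does not decide it. Sequence shared with the Alu repeat is a candidate explanation: 18 of the 21 leading _x_at probe sets stayed above the cutoff on replicate 1, as the Alu control did, against 3 of the 21 unmarked probe sets with the highest signals (Fisher's exact p = 6.7e-06). The _x_at probe sets had the higher mean log2 signal on replicates 2 to 4, 12.70 against 11.06, so part of this contrast could follow signal alone. The probe sets were read on the same array and may share sequence. They are not independent, so this p does not measure the strength of the Alu explanation. Probe sequences, which would settle the question, were not used here.

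Replicate 4 had spike-in signals 6.66-fold lower at the median than the mean of replicates 2 and 3. A dimmer scan or a lower scale factor is argued against, since the median detected gene was 0.94 log2 units higher on replicate 4 and 88.8% of detected genes were higher. Higher nonspecific signal stays open: the median of 137 photoreceptor and liver probe sets differed by -0.29 log2 units, but the quartiles of -0.99 and 0.52 allow a rise, and the olfactory receptor cutoff was highest on replicate 4 (4.66, against 4.29 and 3.91). More labelled human RNA per spike-in may account for it, with detected genes 3.67 log2 units apart from spike-ins at the median, but no measured RNA amount was used here to test this, and it stays open.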

How the results depend on the processing

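Alternatives run on the fit without replicate 1, and the list test without the variance trend over 4 arrays, were added after seeing the data; the others were planned. The limma count over 4 arrays was 0 under every cutoff, normalization and filter tried, but 25 with a pseudocount of 16 and 105 without the variance trend. Leaving out 1 replicate gave 0 to 965 detected genes, 585 to 2040 genes above the cutoff on every array kept (945 without replicate 4) and 0 to 11 gene lists, with the high end in each case without replicate 1. The median r between arrays was 0.21 to 0.65 and the median rho 0.18 to 0.45, lowest without replicate 2. Requiring 3 of 4 arrays raised the 533 genes above the cutoff to 2544. The count was 182 at the 99th and 946 at the 90th percentile of olfactory receptor probe sets, 203 at a fixed log2 of 5, 19 at a fixed log2 of 7 and 273 without _x_at and _s_at probe sets.

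Without replicate 1, the 965 detected genes became 335 at a fixed log2 of 5, 117 at a fixed log2 of 7, 367 with the photoreceptor and lens cutoff, 357 without _x_at and _s_at probe sets, 387 with a pseudocount of 16 and 369 by the median of a gene's probe sets. The 2040 genes above the cutoff became 1175, 273 and 1119 at log2 5, at log2 7 and without _x_at and _s_at probe sets. With a further replicate left out, detected genes ranged from 301 (without replicate 3) to 1246, genes above the cutoff from 2239 to 3352 (without replicate 2), and lists detected more often from 10 to 12. The 11 lists fell to 7 without _x_at and _s_at probe sets, where translation factors, endosomal, immediate early and interferon-stimulated genes no longer passed. The interferon list was also lost at log2 5, with the photoreceptor and lens cutoff and with a pseudocount of 16. Proteasome and heat shock genes passed under several settings, such as the 90th percentile (adjusted permutation p = 0.0408 and 0.0125). For list variation, 1 list passed without replicate 1, and 2 after quantile normalization, the second being squamous epithelium. Over 4 arrays that test had no genes, 11 lists passed with all measured members and 1 without replicate 1; it was not run without replicates 2, 3 or 4, which left no detected gene.

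Under the alternatives to the fit without replicate 1 that were run for them, the lists that passed in it and the detected genes named turned direction only at a fixed log2 of 7, which by construction lies above weak genes. Single genes were not run by the median of a gene's probe sets. Without _x_at and _s_at probe sets, 42 of 105 genes were unchanged and 2 weaker, and the rest had no value. Over 4 arrays, where no list passed, some of the lists that passed without replicate 1 had 0 genes and so lay below their random lists. These were translation factors and the oral cancer panel by the count above the cutoff on all 4, and neutrophil, actin, endosomal, immediate early, interferon and oral cancer panel genes without the variance trend. Lists that had not passed turned under other settings too: proteasome (5 of 35) and monocyte (2 of 21) genes had 0 detected at log2 5, with the photoreceptor and lens cutoff, with a pseudocount of 16 and without replicate 3. By the median of a gene's probe sets, monocyte genes and stroma and vessel genes (2 of 22) had 0 detected. At log2 7 the share detected minus that of random lists was -0.59 percentage points for the respiratory chain, -0.66 for endosomal genes and -0.41 for interferon-stimulated genes. The log2 distance from the cutoff was -0.77 for CLEC7A, -0.93 for CD86, -0.72 for PECAM1, -0.56 for MRPL20, -0.81 for MRPL41, -0.87 for MRPS22, -0.10 for PSMB1, -0.66 for PSMD2, -0.80 for PSMB4, -0.44 for HSPA6, -0.64 for DNAJB1, -0.37 for IRF7, -0.38 for MX2, -0.048 for H2BC12 and -0.72 for H1-2. The cause of the other changes was not tested. Median-centring moves each array's cutoff with its values, so it tests nothing for detection. Signal over background limits these calls: in simulation over 3 arrays, 43.3% of probe sets at 2 log2 units above the cutoff were found.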

Other observations

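The genes of both paragraphs were chosen after their values were seen, and no test of an explanation is given in this part. The 20 genes outside the fixed lists with the highest signals on replicates 2 to 4 by probe sets other than _x_at and _s_at were not tested for a shared theme. INKA1, NICN1 and PPP1R3E led, with log2 signals of 11.74 ± 0.65, 11.003 ± 1.47 and 10.89 ± 1.61 (SD, n = 3). The anti-inflammatory annexin ANXA1 had 10.18 ± 0.22 and LITAF, which lipopolysaccharide induces, 9.87 ± 0.93. SOCS3, an inhibitor of cytokine signalling, had 9.23 ± 0.49, the transcription factor gene CEBPB 9.07 ± 0.67, the cytokine gene OSM 8.61 ± 0.65 and PTGS2, the inducible cyclooxygenase, 8.30 ± 1.00. SFN, the 14-3-3 protein of epithelia, had 9.11 ± 0.40 by an _i_at probe set, CSTB, cystatin B, 8.75 ± 0.24, and WAS, an actin regulator of blood cells, 8.01 ± 0.70 by an _r_at probe set. The others were GNG10, BASP1, RND3, RNASET2, ARLN, WDR26, RPUSD3 and GLTP.

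Of the 965 genes detected without replicate 1, 249 had a probe set above the cutoff on replicate 1, and some of these read as high there as on other arrays. CA6, the carbonic anhydrase secreted into saliva, had signals of 337, 442, 610 and 516 on replicates 1 to 4, unlike SMR3B, STATH, MUC7 and PRB4, which read 1.57 to 3.55 on replicate 1; 1 of its 2 probe sets was detected. PPP1R3E had 2838, 4661, 2687 and 541, WDR26 495, 545, 291 and 116, RPUSD3 470, 542, 325 and 100.5, and EGFR 493, 258, 163 and 126. PSG1, read by an _x_at probe set, had 2977, 5076, 2307 and 1288. For PPP1R3E and PSG1, 1 of 3 probe sets was detected each. It was 2 of 5 for WDR26, 1 of 5 for RPUSD3 and 2 of 9 for EGFR. The signals given are those of 1 probe set per gene and cannot be taken as levels of these genes. In these last 5 genes replicate 4 was the lowest array, as it was for the spike-ins. They are not typical: 88.8% of all detected genes were higher on replicate 4 than on the mean of replicates 2 and 3. The share of such genes among the 249 is not given. ABCC9, a potassium channel subunit that was not detected, read 227 on replicate 1 alone by 1 of its 5 probe sets, and 3.42, 2.30 and 3.71 on the others.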
